A study of Mus musculus with 12 samples.

How the data were processed

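H3K79me2, the dimethyl mark that the methyltransferase DOT1L places on histone H3, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in CD8 T cells isolated from male mice. Per the labels, the mice were wild type for the Cre and floxed Dot1l alleles and carried the OT-I T cell receptor transgene on 1 allele. The cells were activated with antibodies against CD3 and CD28 and grown until day 8 with 0.1% DMSO, EPZ-5676 or SGC-0946. Both compounds inhibit DOT1L by competing with its methyl donor, S-adenosylmethionine, and EPZ-5676 is also called pinometostat. The labels give the dose of each compound as 10 mM, a doubtful unit, since such compounds are given to cells at micromolar doses. Yeast chromatin with HA-tagged histone H3 was added before immunoprecipitation as an external reference. The 12 libraries were 6 immunoprecipitates and 6 inputs, with 2 biological replicates in each of the 3 treatments.

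The deposited data were 3 lists of broad peaks, 1 per treatment, named here the DMSO, EPZ and SGC lists. The submitters' processing notes name BWA 0.7.17-r1188, Picard and MACS2 2.2.7.1 and the builds mm10 (GRCm38) and sacCer3. How the 2 replicates of a treatment were combined, whether the inputs served as background, whether the yeast reads scaled the lists, and the calling thresholds are not given in the sources used here. Each list was taken as pooled over its treatment. The deposited fold enrichment of a peak is the authors' ratio over background, as the layout of MACS2 broad peaks gives it, averaged over the peak. The deposited −log10 p and −log10 q values are the authors' and are likewise averages over a peak. The deposited score column was checked and equals 10 times the −log10 q, rounded down, in all peaks but 1 of the EPZ list. The score was not used further. Fold enrichment was used only to describe, rank or filter peaks within its own list, except where −log10 p was set side by side for peaks of equal fold enrichment and in tests of explanations in the closing section, because the lists may differ in depth and background. Read depth per library is unknown from these lists, so no value has an interval that reflects depth. How low depth affects a list is that weak peaks go uncalled, and a gene without a peak is therefore a gene where none was called.

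Peaks of different lists were compared by overlap of at least 1 base. Shares of peaks or genes have exact (Clopper-Pearson) 95% intervals, which cover counting of peaks or genes only. With 1 pooled list per treatment no test across replicates could be made, and no p-value is given. The overlap under random placement was taken from 1000 random placements of the other list, with each peak kept on its chromosome. Peaks could fall anywhere on it, in or outside genes. Of DMSO and EPZ peaks 95.5% and 96.7% lay in protein-coding genes. This reference is therefore lower than placement within genes would give. Gene positions came from a table of RefSeq genes on GRCm38, the same build as mm10, with 21900 protein-coding genes. A gene was called marked when at least 1 base of a peak lay in it. The intended window, the first 5 kb of a gene, could not be used because the table gives no strand, so the whole-gene rule, listed before as an alternative, became the main one. Exons, introns and UTRs were not analysed here because the table gives no exons.

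The 19 gene lists, with 371 members, were fixed before the data were examined, as were the overlap rule, the alternatives marked below as set in advance and the rule for naming genes. They covered T cell, cytotoxic, memory, metabolic, cell cycle and chromatin genes and markers of CD4 T, B, NK and myeloid cells and of non-hematopoietic tissue. Of these members 366 were protein-coding and 5 were receptor or immunoglobulin constant regions or a pseudogene, which were counted apart. For marking in DMSO, the share of marked members was placed as a percentile among 10000 random lists of the same size from all protein-coding genes. For the share of DMSO-marked members with an EPZ peak, the random lists came from DMSO-marked genes and were matched on the decile of DMSO peak bases in the gene. The alternative set in advance matched on the decile of DMSO fold enrichment. A percentile above 97.5 or below 2.5 was taken as outside the central 95%. The percentile that a list would reach with every DMSO-marked member overlapped was computed after seeing the data, to show where the measure was saturated. For EPZ peaks, lists with fewer than 5 DMSO-marked members got counts only, as did all lists for SGC peaks, since the SGC list marked fewer than 50 genes.

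Genes were named by a fixed rule. It took the 10 protein-coding genes of highest DMSO fold enrichment with an EPZ peak, the 10 without one, and the 10 of highest EPZ fold enrichment without a DMSO peak. It also took the genes or positions of the 15 SGC peaks of highest fold enrichment and, from each list, the marked members of highest and lowest DMSO fold enrichment with and without an EPZ peak, and Dot1l. A gene's fold enrichment is that of its highest peak in the list. Genes named outside this rule are said to be so in the text, are members of a described list or family, or lie at a described set of peaks. Such sets are the widest peaks, the EPZ peaks off DMSO peaks and the SGC peaks.

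Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and the plots matplotlib 3.10.9. The overlap code was tested on simulated data with 2400 intervals, and 0 had a wrong number of shared bases. The list percentile was tested on simulated data for the EPZ comparison, with 300 lists of 20 members each among the 7563 DMSO-marked genes. Of lists with unchanged sharing, 5.33% fell outside the central 95%. With sharing set to 90%, 66.0% of lists were found above it, and with sharing set to 20%, 98.7% were found below it. In this simulation sharing depended only on the decile of DMSO peak bases, the quantity that was matched. It therefore checks the code and cannot show how often lists fall outside when sharing depends on fold enrichment, as it did in the data. Alternatives set in advance were a −log10 q of at least 5, peaks of at least 1 kb, chromosomes 1 to 19 and X only, joining of peaks less than 1 kb apart, overlap of at least 50% of a peak, and other matchings. Alternatives chosen after seeing the data were at least 500 bases of peak in a gene, assignment of each peak to the gene it overlaps most, the thresholds of the SGC list required of every list, and matching on gene length, on 50 bins of fold enrichment, or on fold enrichment and peak bases together.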

Results

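The series asked what inhibition of DOT1L does to H3K79me2 in CD8 T cells, by setting EPZ-5676 and SGC-0946 against the DMSO vehicle after 8 days of expansion. The 3 treatments had 2 immunoprecipitated and 2 input libraries each, and the values come from 1 pooled list of broad peaks per treatment. The read depth behind each list is unknown. Spread between replicates is therefore not measured in any value below, and fold enrichment is the authors' value for a peak within its own list. All positions are on mm10 (GRCm38).

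In vehicle-treated cells, H3K79me2 peaks covered the genes of T cell identity, proliferation and protein synthesis and left the myeloid and non-hematopoietic lists empty. All 17 protein-coding members of the T cell receptor and identity list were marked, among them Ptprc, which encodes CD45, at a fold enrichment of 12.7, the kinase gene Lck at 11.6, Cd8a at 10.6 and Cd6 at 4.84. The receptor constant regions Trac and Trbc1, counted apart, had peaks of 11.6-fold and 13.0-fold. All 30 cytosolic ribosomal protein genes, all 26 cell cycle genes, all 22 splicing and transcription genes, all 18 glycolysis and Myc genes, all 18 naive and memory genes and all 15 homing and adhesion genes were marked. Against these, 0 of 17 myeloid, 0 of 20 non-hematopoietic and 0 of 16 Hox and Meis1 genes had a DMSO peak.

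The DMSO list held 12578 peaks over 68.4 Mb, with a median width of 2420 bases (interquartile range 1011 to 6094) and a median fold enrichment of 3.36. Peaks lay in 7563 of 21900 protein-coding genes (34.5%, 95% interval 33.9 to 35.2), and 95.5% of peaks touched such a gene. In 1739 of the marked genes (23.0%) the highest peak also covered another protein-coding gene, so the mark cannot be given to 1 of them alone. Its widest peak spanned 175.5 kb at Bcl2, the anti-apoptotic gene, on chromosome 1 from 106541660 to 106717205, followed by 147.0 kb at Ankrd11, 143.7 kb at Fyn and 127.5 kb at Mbnl1. Of the 19 gene lists, 11 stood above the 97.5th percentile of random lists in their share of marked members and 4 stood below the 2.5th.

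Among the lists tied to CD8 function, marking in DMSO was uneven. Cytotoxic effector genes were marked in 11 of 20 cases (55.0%, 95% interval 31.5 to 76.9), at percentile 96.5, which moved to between 97.5 and 99.96 under 5 other settings and to 80.3 (8 of 20) when each peak was given only to the gene it overlaps most. Gzmb, encoding granzyme B, had the highest value at 11.1-fold and Id2, Tbx21 and Eomes, transcription factors of effector cells, were marked at 10.8, 8.27 and 6.80, whereas Gzma, Prf1, Ifng, Prdm1 and Klrg1 had no peak. Inhibitory receptor and exhaustion genes were marked in 6 of 15 cases (percentile 67.8), with Ctla4 at 5.95 and Tox at 2.74, and Pdcd1, Havcr2, Lag3 and Tigit had none. Cytokine receptor and JAK-STAT genes were marked in 22 of 23 cases, led by Cish, a feedback inhibitor of cytokine signalling, at 13.3, with Tyk2 the exception. Antigen presentation and interferon genes were marked in 17 of 21 cases, with B2m at 14.0, and Irf7, Isg15, Ifit1 and Ifit3 had no peak. Mitochondrial respiration genes were marked in 19 of 21 cases and DOT1L partners and chromatin modifiers in 25 of 26, from Dnmt1 at 13.8 down to Aff3 at 2.66, with Ell2 unmarked.

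Of the markers of other lymphocytes, NK cell receptor and CD4 T cell genes stood within random lists in their share marked, which over all protein-coding genes was 34.5%, and B cell genes stood below them. NK cell receptor genes, some of which activated CD8 T cells also express, were marked in 5 of 16 cases (percentile 40.5), namely Klrd1, Klrk1, Cd226, Klre1 and Tyrobp, the last through 0.698 kb of a peak shared with neighbouring genes. CD4 helper and regulatory T cell genes were marked in 3 of 12 cases (percentile 25.8), which were Gata3 at 6.22, Ikzf2 at 2.73 and Cxcr5 at 2.60, and Cd4, Zbtb7b and Foxp3 had none. Of 13 B cell genes 1 was marked, Cd79a, through 0.254 kb of a 13.0 kb peak shared with a neighbouring gene. That list stood at percentile 1.64, and at 20.2 when a −log10 q of at least 5 was required. Ighm, the immunoglobulin mu constant region, was counted apart from the protein-coding members and had a DMSO peak of 13.6-fold.

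**Figure D1:**
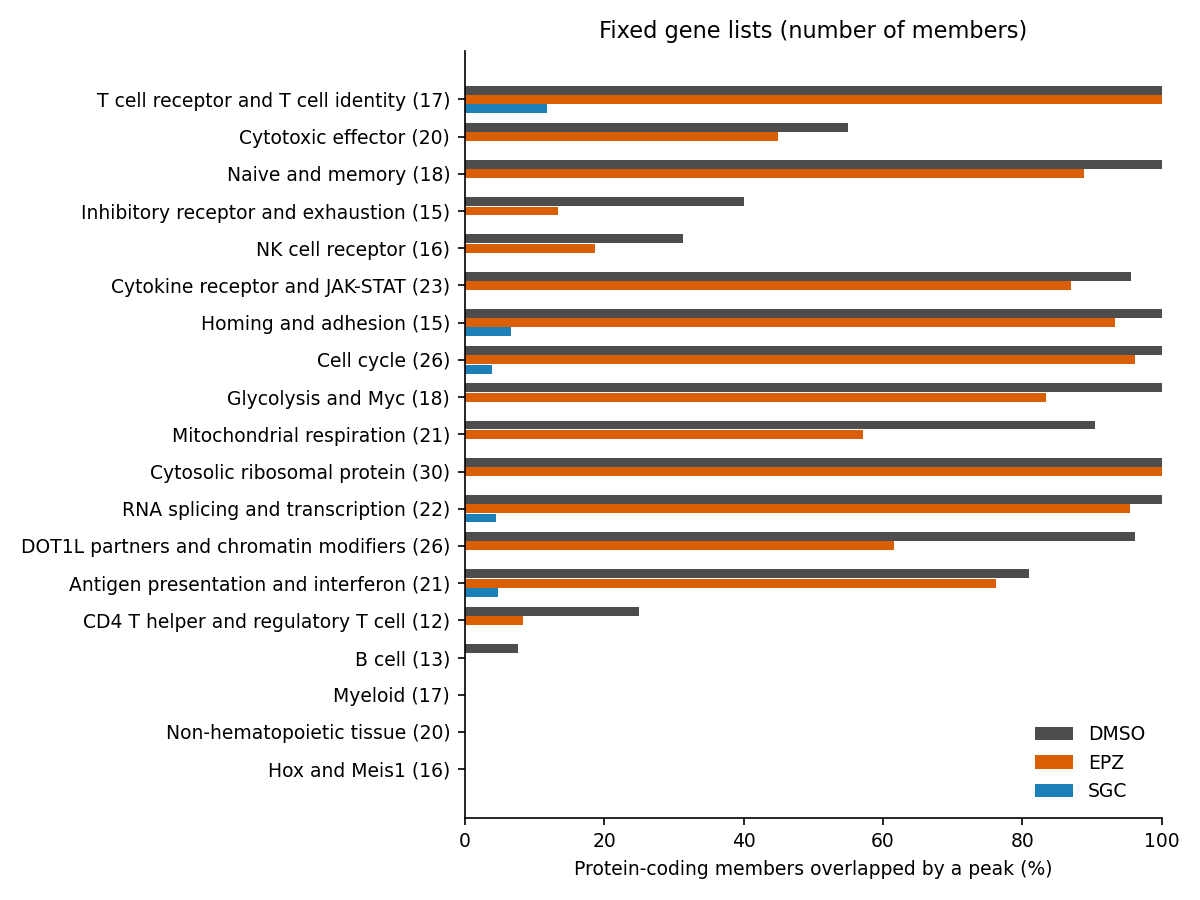
Share of the protein-coding members of each fixed gene list that overlap a peak (percent, horizontal axis), with the number of members in parentheses and 1 bar each for the DMSO, EPZ and SGC lists. T cell identity and cytosolic ribosomal protein genes reach 100% in both the DMSO and EPZ lists, and no list passes 11.8% in the SGC list.

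With EPZ-5676, far fewer regions carried a called peak, and those that did were the regions of strongest DMSO signal. The EPZ list held 4443 peaks over 18.1 Mb, which is 35.3% of the number and 26.4% of the covered length in DMSO. EPZ peaks overlapped 3382 of the 12578 DMSO peaks (26.9%, 95% interval 26.1 to 27.7), against a mean of 1.74% under random placement. Nearly all EPZ peaks, 4436 of 4443 (99.8%), lay on a DMSO peak, and the other 7 included short peaks in Gpr15, Gvin1 and Gm4070. Of the 7563 genes marked in DMSO, 3486 (46.1%, 95% interval 45.0 to 47.2) had an EPZ peak and 4077 had none, while 0 protein-coding genes were marked in EPZ alone.

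Genes with the highest DMSO fold enrichment and an EPZ peak were Lfng, a glycosyltransferase that modifies Notch receptors, at 16.5 in DMSO, and Fam78a, Ptma, Shisa5, Trex1, Msl2, Ptbp1, Plppr3, Mbnl1 and Vps37b, at 15.5 down to 14.9. Lfng lies on chromosome 5 from 140607341 to 140615545, and its EPZ peak had a value of 24.6 within the EPZ list. Shisa5 and the exonuclease gene Trex1 shared 1 DMSO peak, as did Plppr3 and Ptbp1, a repressor of splicing. Mbnl1, a splicing regulator on chromosome 3 from 60472559 to 60629750, held the EPZ peak of highest fold enrichment, 40.96, and EPZ peaks covered 130.9 kb of it against 145.2 kb in DMSO. In genes marked in both lists the EPZ peaks covered a median of 34.4% of the bases that the DMSO peaks covered (interquartile range 18.4 to 55.4). At Bcl2 the widest EPZ peak spanned 101.3 kb.

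The 10 genes of highest DMSO fold enrichment without an EPZ peak were Atrip, Prrt2, Cand2, Tnp2, Atpsckmt, Crybg2, Slc26a10, LOC115489044, Fam71b and Flot1, from 15.2 down to 9.86. All 10 overlapped a DMSO peak that also covered another protein-coding gene, with between 0.025 kb (Atrip) and 2.28 kb (Fam71b) of that peak inside the named gene. Atrip, for example, lay beside Trex1. Among genes whose highest peak covered no other protein-coding gene, 45.2% of 5824 had an EPZ peak. Those of highest DMSO fold enrichment without one, named after their values were seen, included Lrrc75a at 8.88 and Thumpd3 at 8.42. Only 0.365 kb of the 2.49 kb Lrrc75a peak lay in the gene. The Thumpd3 peak ran to 113076327, past the gene's end at 113068278. Others had their highest peak wholly inside the gene. They included Fut7, a fucosyltransferase of selectin ligand synthesis, at 7.36, the mitochondrial genes Atp5e and Txn2 at 6.95 and 6.47, and the GTPase gene Hras at 6.22. Dot1l itself, on chromosome 10 from 80755101 to 80795461, had a DMSO peak of 10.4 kb and 5.09-fold near its lower coordinate and 2 EPZ peaks within that interval, of 0.992 kb at 4.45-fold and 1.96 kb at 2.79-fold. A stronger DMSO peak of 7.89-fold reached only 0.844 kb into Dot1l from its neighbours.

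Overlap with EPZ peaks rose steeply with DMSO fold enrichment. In the 5 lowest deciles of DMSO fold enrichment at most 0.795% of peaks were overlapped (3.25% in the lowest with a −log10 q of at least 5), and the next deciles reached 3.34%, 17.2%, 56.1% and 91.0%. In the highest decile, with values of 6.56 or more, 1252 of 1258 DMSO peaks (99.5%, 95% interval 99.0 to 99.8) were overlapped. Overlapped DMSO peaks had a median fold enrichment of 5.90 and a median width of 8987 bases, against 3.08 and 1546 bases for the rest. By width the share ran from 0.477% in the narrowest decile (12.7% with a −log10 q of at least 5) to 87.0% in the widest, which a rule of 1 base favours. Requiring a −log10 q of at least 5 left 3375 DMSO and 1647 EPZ peaks and 3786 and 1682 marked genes, and requiring overlap of at least 50% of the DMSO peak lowered the overlapped share to 8.48%, and to 66.1% and 30.6% in the highest deciles of fold enrichment and width.

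**Figure D2:**
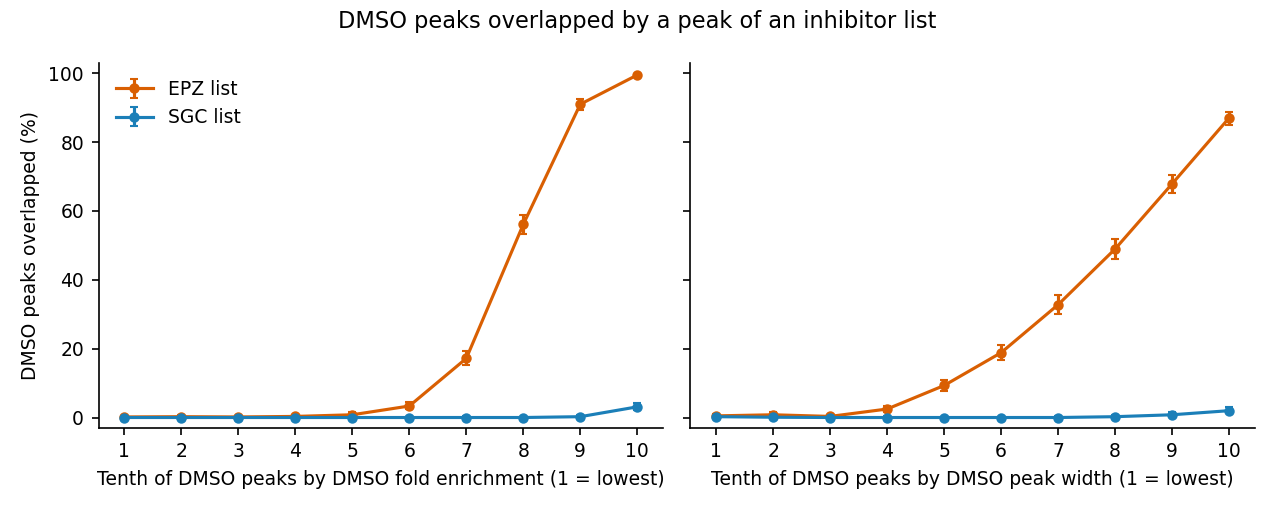
Percent of DMSO peaks overlapped by a peak of the EPZ or SGC list (vertical axis) in deciles of DMSO fold enrichment (left) and DMSO peak width (right); error bars are exact 95% intervals. For EPZ the share climbs from 0.159% in the lowest to 99.5% in the highest decile of fold enrichment, and for SGC the highest decile reaches 3.10%.

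Among the 14 gene lists with at least 5 DMSO-marked members, the share of those members with an EPZ peak ran from 33.3% of inhibitory receptor genes to 100% of T cell identity and cytosolic ribosomal protein genes, against 46.1% of all DMSO-marked genes. Lists were not tested against each other. Percentiles below place each list first among random lists matched on DMSO peak bases and then among lists matched on DMSO fold enrichment. By chance 0.7 lists are expected outside the central 95%, if members are separate draws, although some share a peak, such as Cd3d and Cd3g. Of the 14 lists 10 stood above the 97.5th percentile in the matching on peak bases and 5 in the matching on fold enrichment. These 5 were cytosolic ribosomal protein genes (30 of 30, percentiles 100 and 98.9), cell cycle genes (25 of 26, 100 and 99.4), homing and adhesion genes (14 of 15, 99.9 and 99.6), naive and memory genes (16 of 18, 99.7 and 99.7) and glycolysis and Myc genes (15 of 18, 98.6 and 98.6). In the naive and memory list, S1pr1, Klf2, Ets1 and Tcf7 had EPZ peaks, and the 2 members without were Id3, an inhibitor of E-protein transcription factors, and Slamf6. The naive and memory call ended, at percentile 95.8, when a −log10 q of at least 5 was required, and the homing and glycolysis calls ended, at 97.23 and 96.9, when random lists were matched on fold enrichment and peak bases together. Rps14 and Rps4x had the highest and lowest DMSO values of the ribosomal list, at 13.1 and 4.46. Cdk2 was the 1 cell cycle gene without an EPZ peak, Itga4 the 1 homing gene, and Slc2a3, Pfkl and Slc16a3 the 3 glycolysis genes.

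Another 5 lists stood above the 97.5th percentile only in the matching on peak bases. For T cell identity and for splicing genes the matching on fold enrichment could not give a call above the bound, since with every marked member overlapped they would reach percentiles of only 92.7 and 94.7. All 17 T cell receptor and identity genes had an EPZ peak (percentiles 99.8 and 92.6, and 97.48, just below the bound, with the SGC thresholds required of every list), with Ptprc at 37.6 in the EPZ list and Cd5 at 2.88. Of 11 marked cytotoxic effector genes 9 had one (99.7 and 41.03), including Gzmb, Fasl, Tbx21 and Eomes, and the 2 without were Lamp1 and Gzmm, the latter marked in DMSO through 0.661 kb of a peak shared with a neighbour. Cytokine receptor and JAK-STAT genes had EPZ peaks in 20 of 22 cases (99.8 and 97.3), all but Jak2 and Stat5a. For splicing and transcription genes the count was 21 of 22 (99.95 and 75.4), all but Polr2b, and for antigen presentation and interferon genes 16 of 17 (99.96 and 95.8), all but Stat2.

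The remaining 4 tested lists stood inside the central 95% under both matchings. DOT1L partners and chromatin modifiers had EPZ peaks in 16 of 25 cases (64.0%, 95% interval 42.5 to 82.0, percentiles 15.8 and 96.5). The 9 without were Mllt1, Mllt3, Mllt10, Aff1, Aff3, Aff4, Men1, Dnmt3a and Kdm2b, with DMSO values of 3.76 or less, and several of them encode subunits or partners of DOT1L-containing or super elongation complexes. Mitochondrial respiration genes had EPZ peaks in 12 of 19 cases (95.7 and 36.6), from Cox5a, at 7.95 in DMSO, to Sdha, at 4.63. Inhibitory receptor genes had them in 2 of 6 cases, Ctla4 and Btla (60.4 and 73.7), and NK cell receptor genes in 3 of 5, Klrd1, Klrk1 and Cd226 (71.8 and 73.3). Of the lists too small to place, Gata3 was the 1 of 3 CD4 T cell genes with an EPZ peak and Cd79a, the 1 B cell gene, had none, while Ighm had an EPZ peak of 16.5-fold in its own list.

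With SGC-0946 few peaks were called, and among protein-coding genes Mbnl1 and Ptprc held the most bases of them. The SGC list held 55 peaks over 0.138 Mb, 0.437% of the number and 0.202% of the covered length in DMSO, and it marked 31 protein-coding genes (0.142%, 95% interval 0.0962 to 0.201). Mbnl1 carried 6 SGC peaks over 30.4 kb and the signalling phosphatase gene Ptprc carried 15.7 kb. Others with more than 1 kb included Stk17b, Srsf3, Ikzf1, Ms4a4b, Ugcg, Grap2, Selplg, Lfng, the proliferation marker Mki67 and B2m, whose peak also covered Patl2. Actb, Bcl11b, Pim1 and Gimap4 were marked over less than 1 kb. Members of the fixed lists with an SGC peak included Ptprc of the T cell list, Selplg of the homing list, Mki67 of the cell cycle list, Srsf3 of the splicing list and B2m of the antigen presentation list. No cytotoxic, memory, cytokine receptor, glycolysis, mitochondrial, ribosomal or chromatin list member had one, and neither did Dot1l.

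By fold enrichment within the SGC list, the highest peak lay outside any annotated gene, on chromosome 18 from 65427484 to 65427794, with 311 bases at 13.0-fold. The next, 271 bases at 7.84-fold, lay on chromosome 5 from 149247971 to 149248241 at Gm24105. These were followed by Mbnl1 (chromosome 3, 60474427 to 60485824) at 6.67 and the T cell receptor beta locus over Trbc1 (chromosome 6, 41534455 to 41539683) at 5.87. Next came Ano2 at 5.73, through a peak of 318 bases, Stk17b at 5.42 and Ptprc at 5.41. An interval on chromosome 17 from 34000700 to 34001281, at 5.26, lay in no annotated gene. It began just past the end of H2-K1 at 34000619 and lay on the DMSO and EPZ peaks of H2-K1. Srsf3, Mbnl1 again, Actb, the noncoding RNA gene Chaserr, Ikzf1, Ms4a4b and Selplg completed the 15 highest, from 5.11 down to 4.60. Of all 55 peaks 41 lay in protein-coding genes (74.5%), 11 in other annotated genes only, including Tcra, Tcrb, Igh and Malat1, and 3 in none.

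Every SGC peak, 55 of 55 (95% interval 93.5 to 100), lay on a DMSO peak, against a mean of 3.78% under random placement, and 51 of them lay on DMSO peaks in the top 10% by fold enrichment. Seen from the DMSO list, 42 peaks (0.334%, 95% interval 0.241 to 0.451, and 0.0318% when at least 50% of the peak had to be covered) were overlapped, 39 of them in the highest decile of fold enrichment and 3 in the next. At the same fold enrichment of 3.4 to 4.0, the median −log10 p was 4.135 in the SGC list, 4.78 in the DMSO list and 5.57 in the EPZ list. With a −log10 q of at least 5, 9 SGC peaks and 5 genes remained.

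**Figure D3:**
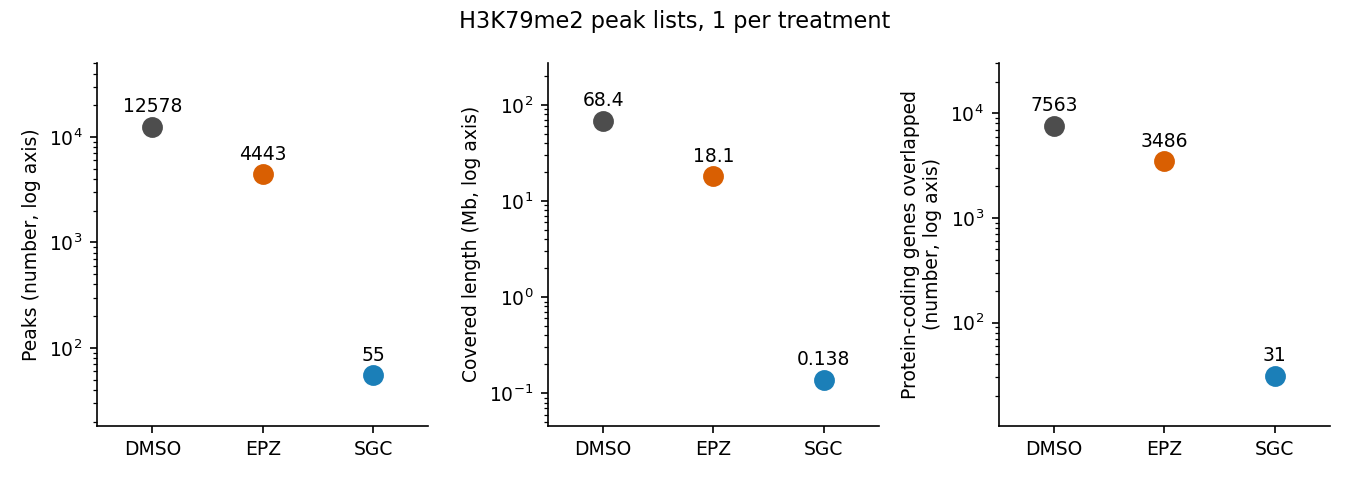
Number of peaks, covered length in Mb and number of overlapped protein-coding genes for the DMSO, EPZ and SGC lists, each on a log axis, with 1 point per pooled list and no error bars because replicates were pooled. Counts run from 12578 through 4443 to 55 peaks and from 7563 through 3486 to 31 genes.

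The inhibitors, compared at the same labelled dose (10 mM, a doubtful unit) and the same day, differed in the number of called peaks, and the few SGC peaks lay on the strongest EPZ peaks. The SGC list held 1.24% as many peaks as the EPZ list and 0.763% of its covered length. Of the 55 SGC peaks 54 (98.2%, 95% interval 90.3 to 99.95) overlapped an EPZ peak, the exception being the chromosome 5 interval at Gm24105, and 52 lay on EPZ peaks in the top 10% by fold enrichment. Conversely 41 of 4443 EPZ peaks (0.923%, 95% interval 0.663 to 1.25, and 0.0900% when at least 50% of the peak had to be covered) were overlapped by an SGC peak. The EPZ peaks under SGC peaks had a median rank of percentile 99.1 by fold enrichment within the EPZ list. All 31 genes marked in SGC were marked in EPZ. Independent lists within the 7563 DMSO-marked genes would share 14.3, and random lists matched on DMSO fold enrichment shared a mean of 29.4 (range 23 to 31), since both comparisons use the same DMSO list.

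At Mbnl1, Ptprc and Bcl11b each SGC peak lay inside an EPZ peak and a DMSO peak. At Ptprc, on chromosome 1 from 138062859 to 138175756, peaks covered 78.0 kb in DMSO, 60.2 kb in EPZ and 15.7 kb in SGC. At Bcl11b, a transcription factor gene of T cell commitment on chromosome 12 from 107910403 to 108004145, they covered 90.3, 84.3 and 0.576 kb. Bcl11b was named outside the fixed rule. Across the 31 genes the SGC peaks covered a median of 14.6% of the bases under EPZ peaks (interquartile range 7.12 to 27.8) and 10.7% of those under DMSO peaks. With 1 pooled list per compound no interval of the difference between cultures could be given, and whether it exceeds the spread between replicates is not known.

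**Figure D4:**
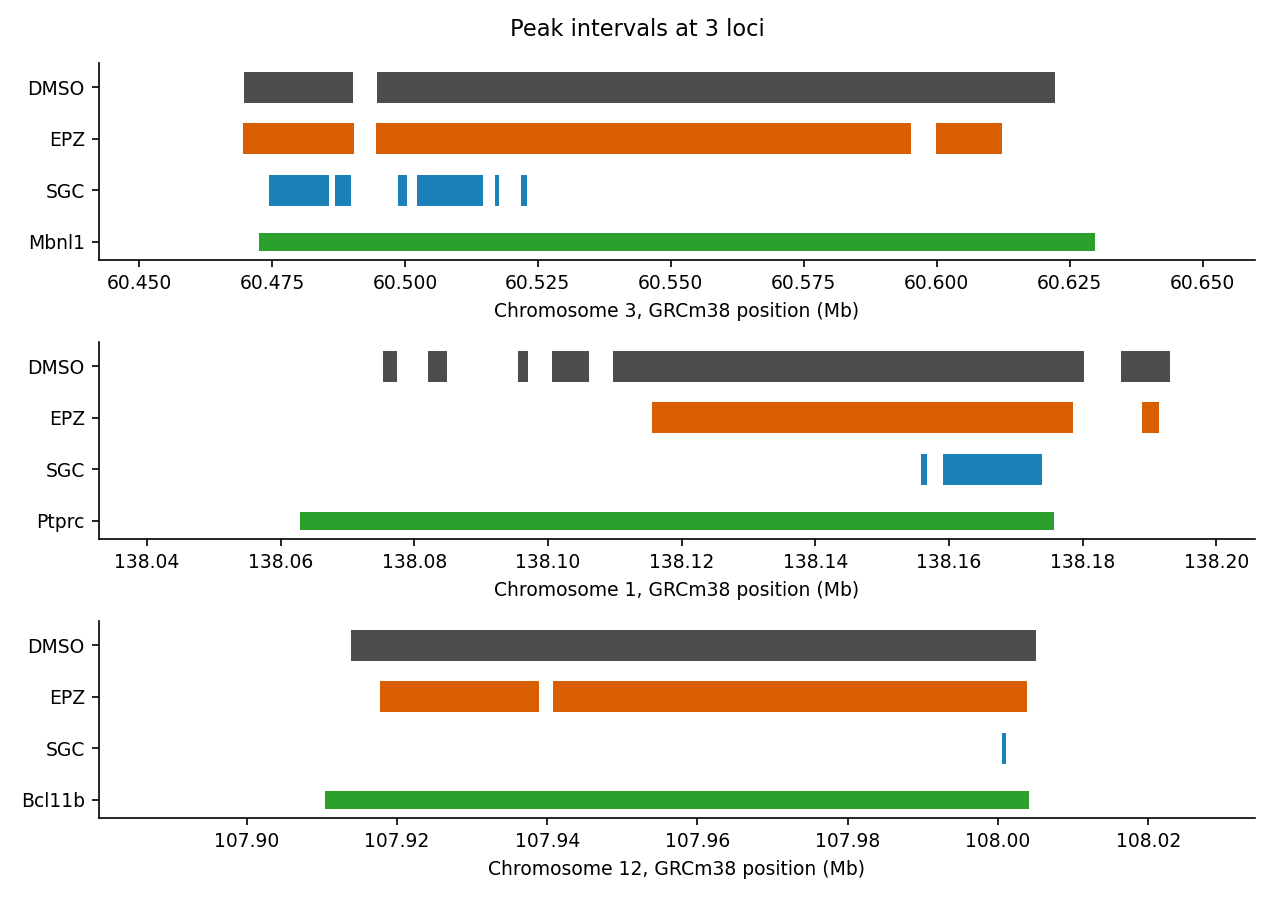
Peak intervals of the DMSO, EPZ and SGC lists (colored bars) along Mbnl1, Ptprc and Bcl11b (green bars show the annotated gene), with the horizontal axis in Mb on the chromosome. SGC intervals cover 30.4 kb of Mbnl1, 15.7 kb of Ptprc and 0.576 kb of Bcl11b, inside the EPZ and DMSO intervals.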

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

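Alternatives chosen only after seeing the data were the SGC thresholds in every list, at least 500 bases of peak in the gene, assignment of a peak to the gene it overlaps most, and matching on gene length, on 50 bins of fold enrichment or on fold enrichment and peak bases together. Of 374 values under alternatives, over 53 results, 312 stayed within the tolerance, which was a factor of 1.5 for counts, the exact 95% interval for shares and the same side of the 2.5th and 97.5th percentiles for lists. A percentile inside the central 95% was thus free to move, and mitochondrial overlap went from 95.7 to 25.8 with a −log10 q of at least 5 and cytotoxic marking from 96.5 to 80.3 with each peak given to the gene it overlaps most. Some settings could change little. Joining peaks left 12578 DMSO and 4443 EPZ peaks, as before, and chromosomes 1 to 19 and X kept 12572 and 4441. Their values count among the 312 and say little about robustness. The order DMSO, EPZ, SGC in peaks and genes held under each setting run. Requiring a −log10 q of at least 5 left 3375 DMSO peaks (41.8 Mb), 1647 EPZ peaks and 9 SGC peaks (0.0458 Mb), and 3786, 1682 and 5 genes. EPZ peaks then overlapped 46.7% of DMSO peaks, DMSO peaks 99.0% of EPZ peaks, SGC peaks 0.486% of EPZ peaks and EPZ peaks 88.9% of SGC peaks. By fold enrichment the lowest and highest deciles of DMSO peaks were overlapped by EPZ in 3.25% and 98.2%, by width in 12.7% and 77.8%, and 44.1% of DMSO-marked genes had an EPZ peak. Cytotoxic marking then stood at percentile 99.96, B cell marking at 20.2 and naive and memory overlap at 95.8. This setting removes weak peaks by construction. With peaks of at least 1 kb, SGC kept 27 peaks and 19 genes, the EPZ share of DMSO peaks was 29.1% and of DMSO-marked genes 41.9%, the SGC share of DMSO and EPZ peaks 0.232% and 0.650%, the EPZ share of SGC peaks 100%, cytotoxic marking stood at 98.4 and B cell marking at 3.13. With the SGC thresholds in every list, 6689 DMSO and 2889 EPZ peaks passed, EPZ overlapped 38.6% of DMSO peaks and DMSO 99.6% of EPZ peaks, 43.0% of DMSO-marked genes had an EPZ peak, T cell identity overlap stood at 97.48, just below the bound, cytotoxic marking at 99.1 and B cell marking at 4.53. Overlap of at least 50% of the tested peak gave 8.48% for DMSO by EPZ, 0.0318% for DMSO by SGC, 0.0900% for EPZ by SGC, and 66.1% and 30.6% for the highest deciles of fold enrichment and width. At least 500 bases in the gene gave 44.7% of DMSO-marked genes with an EPZ peak and cytotoxic marking at 97.75, and matching on gene length put cytotoxic marking at 97.53. The overlap of lists with EPZ depended most on the matching. In the order fold enrichment, 50 bins of it, and fold enrichment with peak bases, T cell identity stood at 92.6, 91.6 and 68.9, cytokine receptors at 97.34, 97.36 and 88.9, splicing at 75.4, 74.6 and 49.5, and antigen presentation at 95.8, 95.2 and 95.6. Cytotoxic effectors went to the other side of the middle, at 41.03 and 39.6, and to 55.7. With every marked member overlapped, T cell identity and splicing would stay below the 97.5th percentile in all 3 of these matchings and cytotoxic effectors in the second, so no call was possible there. Cytotoxic effectors, at 81.8%, nonetheless lay near the random means of 83.3%, 83.9% and 79.8%. Splicing genes, at 95.5%, lay near the joint random mean of 95.2%, with 90.8% in the first matching. T cell identity genes, at 100%, had a joint random mean of 97.45%, with 89.98% in the first matching. No clear excess over random lists was thus left for cytotoxic effectors, nor for splicing and T cell identity under the joint matching. Under the joint matching homing stood at 97.23 and glycolysis at 96.9. Apart from fewer or weaker peaks by construction, the cause was not tested. No paired analysis was possible because the 2 replicates of each treatment share numbers across treatments but each list is pooled, and leaving out a replicate was not possible for the same reason. The first 5 kb of a gene, 1 kb around its 5′ end and 500 bases within the first 5 kb were not run, since the gene table has no strand. Unknown depth limits all counts of weak peaks.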

Other observations

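All tests of explanations here, and the families and gene kinds described first, were chosen after the values were seen. Cytosolic and mitochondrial ribosomal proteins parted ways. Of 83 Rpl and Rps genes 79 had a DMSO peak and 77 of those an EPZ peak (97.5%, 95% interval 91.2 to 99.7), the 2 without being Rpl22l1 and Rpl36a. Of 78 Mrpl and Mrps genes, which build the ribosomes of mitochondria, 68 had a DMSO peak and 12 of those an EPZ peak (17.6%, 95% interval 9.47 to 28.8). Their median DMSO fold enrichments were 7.31 and 3.61, and random lists matched on DMSO fold enrichment gave 86.3% and 24.98%, which put the families at percentiles 100 and 1.61 among 11 families looked at. With matching on DMSO peak bases, the main one for gene lists, they stood at 100 and 24.2, so the low place of the mitochondrial family rested on the matching. Zinc finger (Zfp) genes had EPZ peaks in 47 of 182 marked cases (25.8%, percentile 21.2 by fold enrichment and 0 by peak bases), proteasome subunit genes in 26 of 37 (70.3%, 64.8 and 100) and translation initiation factor genes in 37 of 50 (74.0%, 89.0 and 99.97). All 8 Gimap genes, GTPases of lymphocytes, were marked in DMSO and EPZ (percentile 69.5 by fold enrichment, where random lists averaged 94.1%, and 99.5 by peak bases).

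The antigen receptor loci were marked at most of their joining segments and at few of their variable segments. Of 82 J segments 71 had a DMSO peak (86.6%), 70 of them an EPZ peak and 10 an SGC peak, whereas 8 of 394 V segments had a DMSO peak (2.03%) and 4 of these an EPZ peak. J segments share peaks, so these are not counts of separate peaks. The SGC peaks over Trbj1 and over Trbj2 segments, for example, lay on the same DMSO peak of 23.6 kb. The mice carried the OT-I receptor transgene, and whether its reads add to peaks at the T cell receptor loci in any list was not tested. Histone cluster genes had 0 DMSO peaks in 67 genes, although all 26 cell cycle list members were marked. Olfactory receptors had 2 in 1110, vomeronasal receptors 0 in 353 and keratins 0 in 53. Protein-coding genes on chromosome X were marked in 184 of 966 cases (19.1%, 95% interval 16.6 to 21.7), below each autosome, of which chromosome 7 was lowest at 27.3%. On chromosome Y 4 of 256 were marked (1.56%). The cells came from male mice, and whether the lower copy number of X and Y lowers these shares was not tested.

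The SGC list held far fewer peaks than the EPZ list, although both compounds target DOT1L. A stricter threshold in that list is argued against, because 2889 EPZ peaks passed the lowest fold enrichment (3.28) and the lowest −log10 p (3.64) of the SGC list. Lower sequencing depth behind the SGC list may contribute, since its median −log10 p at 3.4 to 4.0-fold was 4.135, below the lower quartiles of the DMSO and EPZ lists (4.43 and 5.11). Depth as the whole cause cannot be told apart from other causes, since 643 EPZ peaks still passed when their −log10 p was scaled to the SGC level and 2 times the SGC fold threshold was required, but the scaling rests on SGC peaks that were called and so does not show the full loss of depth there might be. A stronger loss of the mark with SGC-0946 than with EPZ-5676, and a difference in how the libraries were pooled or scaled to the yeast chromatin, stay open, as neither could be tested on pooled lists.

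Gene lists differed in the share of DMSO-marked members with an EPZ peak. Strength of the DMSO mark, as measured by the fold enrichment of a gene's highest peak, did not account for all lists. Of 14 lists, 11 of which could have passed the upper bound, 5 still stood outside the central 95% when random lists were matched on 50 bins of DMSO fold enrichment. By chance 0.7 are expected if members are separate draws, although some share a peak. Fold enrichment is an average over a peak in 1 pooled list, so matching on it cannot exclude strength itself as the cause. Strength and width of the DMSO mark together left 3 lists outside, the naive and memory, cell cycle and cytosolic ribosomal genes, though the naive and memory call also ended, at 95.8, with a −log10 q of at least 5. Gene length in the whole-gene rule was not put to a test, as matching on it left 10 lists outside, as many as without matching, and moved no random mean by more than 2.63 points. The joint matching could not place T cell identity and splicing genes above the bound, since they would stay below the 97.5th percentile with every marked member overlapped. For splicing genes it left no clear excess, with a share of 95.5% against a random mean of 95.2%. T cell identity genes, at 100%, stood against a random mean of 97.45%, so the joint matching left little excess for them too. What else sets lists apart stays open, with no biological explanation tested.

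The 2 SGC peaks of highest fold enrichment were short and lay outside protein-coding genes, on chromosomes 18 and 5. The chromosome 18 peak was also the highest of the DMSO list, at 17.9-fold, and ranked 147 in the EPZ list. It measured 0.312, 0.303 and 0.311 kb in the DMSO, EPZ and SGC lists, and a short Ano2 peak 0.324, 0.331 and 0.318 kb. The highest Ptprc peak measured 70.5, 63.0 and 14.9 kb. The chromosome 5 peak measured 0.545 kb in DMSO and had no EPZ peak. The shortest peaks of the 3 lists had 280, 303 and 231 bases, so the short peaks had little room to narrow. Short peaks with signal unrelated to gene transcription, such as reads piled up at a repeat, could account for the 2 highest SGC peaks. Of 13 SGC peaks under 400 bases 38.5% (95% interval 13.9 to 68.4) lay outside protein-coding genes, against 21.4% of the 42 longer peaks (95% interval 10.3 to 36.8), the intervals overlap, and without the 2 peaks that prompted the test the share was 3 of 11 (27.3%). Longer peaks outside protein-coding genes included those at the annotated genes Tcrb, Igh, Malat1 and Chaserr, and the 318-base Ano2 peak counted as inside. Lying outside protein-coding genes thus does not measure signal unrelated to transcription, and the share decides nothing. With so few peaks such signal and a signal of the mark itself cannot be told apart, and input tracks were not analysed here.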
